A study of Homo sapiens with 12 samples.

How the data were processed

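Gene expression was measured on 12 Affymetrix HG-U133A arrays, an oligonucleotide array on which each probe set (a group of short probes) reads 1 or more transcripts. The arrays carried RNA of 6 untreated human lymphoma cell lines, with 2 arrays per line. KM-H2, L1236 and L428 were grouped as Hodgkin lines, and Namalwa, SU-DHL4 and SU-DHL6 as B-cell lines, as the labels name them. Per the labels' protocols, biotin-labelled probes were made from 5 ug of total RNA. The series' design text states that KM-H2, L1236, L428 and Namalwa came from a dataset its submitters had published earlier and that SU-DHL4 and SU-DHL6 were newly generated. Dataset and lymphoma type therefore overlap in part, because Namalwa was the only B-cell line in the published dataset and the new dataset held B-cell lines alone.

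The deposited expression table holds log2 values normalised by RMA (robust multi-array average) in R 2.10.1, per the design text and the submitters' processing notes, and its values ran from a lowest of 3.62 to a highest of 14.3. The settings of RMA are not given in the sources used here. A further deposited table holds the authors' own comparison of the Hodgkin and B-cell lines, with p-values, Benjamini-Hochberg adjusted p-values and a log2 difference per probe set. The design text names a moderated test for it, and how the duplicate arrays entered is not given in the sources used here. The table holds no detection calls, so values near the lower quartile of an array (5.64 to 5.75) could not be told from background, and differences that reach into that range understate the fold. The number of arrays limits the precision of every value.

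Of 22283 probe sets, 68 Affymetrix controls were left out and 22215 were tested. The platform annotation gave 1 gene symbol for 19065 probe sets, several for 1043 and none for 2107. Symbols were looked up by Entrez identifier in a RefSeq gene table of assembly GRCh38.p14, where 19053 of the 19065 matched and 0 changed. No coordinates were used from that table, only symbols and which genes neighbour each other, because no genome build belongs to the array values. A gene with several probe sets was represented by the one with the highest mean over the 12 arrays, which gave 11963 genes. All work was done in R 4.3.3 with limma 3.58.1.

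For Hodgkin against B-cell lines, the 2 arrays of a line were averaged first, and limma's linear model with empirical Bayes moderation was fitted to the 6 line means, 3 against 3, two-sided. The line was taken as the replicate because the question concerns lymphoma types. P-values were adjusted by Benjamini-Hochberg over the 22215 probe sets, with a threshold of 0.05. For each line against the mean of the other 2 lines of its type, all 12 arrays entered a single limma fit with a coefficient per line, and calls needed an adjusted p under 0.05 and a log2 difference of at least 1 in size. Whether the duplicate arrays of a line came from separate cultures is not given in the sources used here, so these p-values measure only the spread between duplicate arrays, which may be technical. All adjusted p-values of genes in the text come from limma.

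A set of 24 gene lists was written from general knowledge: B-cell identity, Germinal centre, Immunoglobulin genes, Plasma cell, Secretory pathway and unfolded protein response, NF-kB targets, JAK-STAT pathway, Hodgkin markers with cytokines and checkpoint ligands, AP-1 family, B-lineage antagonists and Notch pathway, MHC class I processing, MHC class II, Interferon response, Cytoskeleton and adhesion, Receptor tyrosine kinases, Apoptosis regulators, Cell cycle, Histone acetylation and deacetylation, Polycomb and DNA methylation, Ribosomal proteins, and 4 lists of markers of other cells, namely T and NK cells, myeloid and dendritic cells, stromal, endothelial and epithelial cells, and erythroid cells and platelets. The lists held 499 entries for 497 distinct genes, 432 of which were measured by a probe set named here. Much of the knowledge behind the Hodgkin, B-cell and NF-kB lists was established on these and similar lines, so their direction is not independent evidence. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided and adjusted over the 24 lists. The test was repeated with the correlation estimated for each list and with fry, which asks whether a list's members move, on balance, one way. With an estimated correlation camera also takes the few residual degrees of freedom of the fit, which makes it stricter by itself. For the JAK-STAT pathway the estimate was 0.0126, close to the preset 0.01, yet camera's unadjusted p rose from 0.00196 to 0.0387. A call lost in that repeat is therefore not by itself a sign that a list's genes vary together. Members past the threshold were counted over all probe sets and adjusted over the list alone.

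Genes named in the text follow a rule fixed, with the tests, the lists and the alternatives, before the data were examined. It takes 18 genes of B-cell, plasma cell and Hodgkin biology whatever their result (16 of them have a probe set named here), the 10 largest differences in each direction among called genes whose line means do not overlap, up to 4 members of each list by smallest p, and the 5 largest differences in each direction per line. Genes named outside the rule are given as such.

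The fits were tested on simulated data built from the real arrays' means and spread over all 22215 probe sets. For Hodgkin against B-cell lines, 64% of probe sets shifted by a log2 of 1 were recovered, 82% of those shifted by 2 and 86% of those shifted by 4, and 6 of 165 calls were false. Treating the 12 arrays as independent gave 435 false calls of 628, and a random block per line gave 145 of 336. For KM-H2 against the other Hodgkin lines, 100%, 98% and 100% of shifts of 1.5, 2 and 4 were recovered, with 0 false calls of 199. In a simulation over 11963 genes camera called the 1 list that had been shifted and 0 others. The simulated genes varied independently of each other. It therefore cannot show how often camera falsely calls lists whose genes vary together, and the estimated correlation reached 0.52 in the real data (MHC class II).

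The alternatives were 12 arrays as independent samples, the line as a random block, the replicate number as a further block, the dataset as a block, the published dataset alone, arrays centred on their medians, repeated quantile normalisation, a floor at each array's 20th percentile, a filter on dim probe sets, an intensity trend in the variance prior, a fold minimum, the mean over a gene's probe sets, and leaving out each line and each array in turn. Because the new dataset held B-cell lines alone, the dataset as a block and the published dataset alone give the same difference for a gene, the mean of the 3 Hodgkin lines minus Namalwa, and are not separate checks. The spread comes from the Hodgkin and SU-DHL lines with the block and from the Hodgkin lines alone within the published dataset, where Namalwa is the whole B-cell arm and is assumed to vary like them. A fit without a line has fewer lines to test with, so a call near the threshold can be lost although the difference stays similar. Levels of XIST and of Y-linked genes were not used.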

Results

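Expression profiles were obtained for 3 cell lines of classical Hodgkin lymphoma and 3 lines of other B-cell lymphomas, all grown without treatment. KM-H2, L1236 and L428 were established from patients with Hodgkin lymphoma, whose tumour cells derive from B cells. Namalwa is a Burkitt lymphoma line, and SU-DHL4 and SU-DHL6 are lines of diffuse large B-cell lymphoma of germinal-centre type. Each line was profiled on 2 arrays, and the question was how expression in the Hodgkin lines departs from that in the B-cell lines, with a view to plasma cell differentiation. Median log2 signal was close to equal on the 12 arrays, from 6.85 to 6.92. Duplicate arrays of a line correlated across probe sets, which are not independent replicates, with r = 0.992 for KM-H2, 0.995 for L1236, 0.995 for L428, 0.993 for Namalwa, 0.992 for SU-DHL4 and 0.981 for SU-DHL6. In SU-DHL6, 465 probe sets (2.09%) lay over 2-fold apart between duplicates, against 17 to 122 in the other lines. The 3' probe set of GAPDH exceeded the 5' one by 0.47 on SU-DHL6 replicate 2 and by -0.09 to 0.16 on the other arrays. For ACTB the difference was -0.15 against -0.71 to -0.40, the direction that lower RNA integrity gives. The B-cell lines resembled each other (r between line means 0.964 to 0.967 across probe sets) more than the Hodgkin lines did (0.930 to 0.945), and pairs across types lay at 0.906 to 0.928. The first principal component, 41.5% of the variance, separated the 6 Hodgkin arrays from the 6 B-cell arrays, and the second, 18.4%, separated KM-H2 from L1236.

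Genes of the B-cell programme were expressed at lower levels in the Hodgkin lines. MS4A1, which encodes the surface antigen CD20, lay at a log2 signal of 6.15 ± 0.12 (SD, n = 3 lines) in Hodgkin and 11.98 ± 0.87 in B-cell lines, 56.6-fold lower (log2 difference -5.82 ± 0.44 SE, adjusted p = 0.0136). CD79A and CD79B, the signalling chains of the B-cell receptor, were lower by 34.3-fold (log2 difference -5.10 ± 0.19, adjusted p = 0.0049) and 16.4-fold (-4.04 ± 0.18, adjusted p = 0.00499). VPREB3, a pre-B-cell receptor associated protein, had a log2 difference of -3.37 (adjusted p = 0.00751), and BTK, a kinase downstream of the receptor, one of -2.67 (adjusted p = 0.00901). Of the 26 measured genes of the B-cell identity list, 10 were lower in the Hodgkin lines and 0 higher, and 19 were lower when adjusted over the list alone. The list median was -2.73 (camera adjusted p = 4.05e-18), and the call held with an estimated correlation (adjusted p = 0.0129). MS4A1 was no longer past the threshold without L428 or SU-DHL6 (adjusted p = 0.0586 without SU-DHL6, range over all alternatives 9.6e-07 to 0.0586), whereas CD79A, CD79B, VPREB3 and BTK kept their calls without any 1 line. With the dataset as a block, MS4A1 (adjusted p = 0.0276), CD79A (0.0255), CD79B (0.0255), VPREB3 (0.0276) and BTK (0.0446) were past the threshold. That block leaves the mean of the Hodgkin lines minus Namalwa alone as the difference (-4.88 for MS4A1), as does the published dataset by itself, where only the Hodgkin lines give the spread. There the adjusted p was 0.0378 for MS4A1, CD79A and CD79B, 0.0723 for VPREB3 and 0.12 for BTK, with no B-cell spread entering.

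The Hodgkin lines were not uniform in this respect. PAX5, the transcription factor that maintains B-cell identity, lay at 9.66 in L1236, close to the 9.81 to 10.4 of the B-cell lines, but at 5.88 in KM-H2 and 5.83 in L428. POU2AF1, a B-cell transcriptional coactivator, showed the same arrangement, with 10.7 in L1236 against 4.99 in KM-H2 and 5.21 in L428. Neither passed the test over the 3 Hodgkin lines (PAX5 -2.92, adjusted p = 0.331; POU2AF1 -4.36, adjusted p = 0.321). Both passed it without L1236, PAX5 with -4.19 (adjusted p = 0.0108, range over all alternatives 0.0108 to 0.792) and POU2AF1 with -6.23 (adjusted p = 0.00556, range 0.00556 to 0.796).

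**Figure D1:**
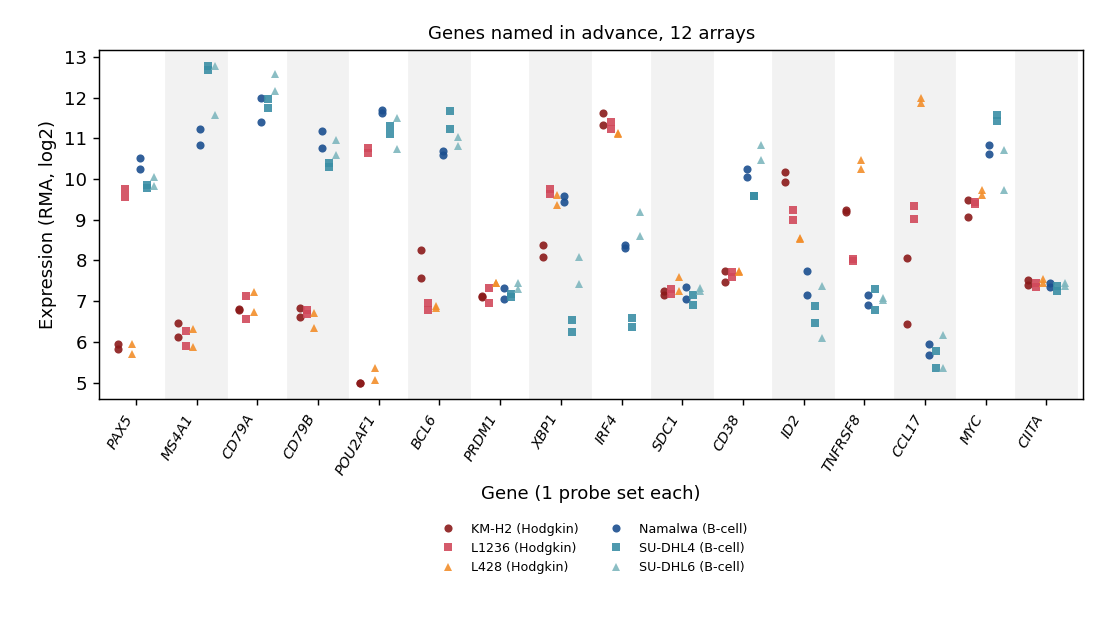
RMA log2 expression (vertical axis) of the 16 genes chosen in advance that have a probe set named here (horizontal axis), with 1 point per array, coloured and shaped by cell line. MS4A1, CD79A and CD79B separate the types, while PAX5 and POU2AF1 in L1236 (line means 9.66 and 10.7) lie near the B-cell lines.

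Genes of the germinal centre reaction were lower in the Hodgkin lines. BCL6, the repressor that establishes the germinal centre state, was 13.9-fold lower (log2 difference -3.79 ± 0.37 SE, adjusted p = 0.0243, n = 3 lines per type). ELL3, an elongation factor expressed in germinal centre B cells, and BCL7A had differences of -2.80 (adjusted p = 0.0193) and -2.40 (adjusted p = 0.0256). Of 12 measured genes of the list, 3 were lower and 0 higher, and 8 were lower when adjusted over the list alone (median -2.44, camera adjusted p = 2.17e-09). This call also held with an estimated correlation (adjusted p = 0.0306). STAP1, a signalling adaptor, missed the threshold (-3.48, adjusted p = 0.0509) and passed it without Namalwa (adjusted p = 0.0373) or L1236 replicate 1 (0.0499), without dim probe sets (0.0297), with an intensity trend (0.0454) and by gene means (0.0457), with a range over all alternatives of 5.6e-05 to 0.197. Calls of the single genes were lost without single lines, where fewer lines also remain to test with. Their differences changed less, at -4.14 to -3.57 for BCL6 and -2.57 to -2.23 for BCL7A without any 1 line. BCL6 and BCL7A were lost without any 1 of L1236, L428, Namalwa, SU-DHL4 and SU-DHL6, with highest adjusted p of 0.0828 for BCL6 (without SU-DHL4, range over all alternatives 4.5e-06 to 0.277) and 0.0803 for BCL7A (without Namalwa, range 9.1e-06 to 0.219). ELL3 was lost without L1236, L428 or SU-DHL6 (adjusted p = 0.0723 without SU-DHL6, range 5.6e-06 to 0.0971). BCL6 (adjusted p = 0.171), BCL7A (0.177) and ELL3 (0.0971) did not pass with the dataset as a block.

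Among markers of plasma cells, the antibody-secreting end of B-cell differentiation, the 2 that passed the threshold were lower in the Hodgkin lines. Such lower levels cannot be told apart here from those of the B-cell genes in general. JCHAIN, the joining chain of polymeric immunoglobulins, was 42.3-fold lower in the Hodgkin lines, at 4.99 ± 0.18 (SD, n = 3) against 10.4 ± 0.13 (log2 difference -5.40 ± 0.12 SE, adjusted p = 0.00106), and CD38, a surface enzyme of germinal centre and plasma cells, was 5.5-fold lower (-2.46 ± 0.27, adjusted p = 0.0314). IRF4, a transcription factor required for plasma cells, had a log2 difference of 3.39 that missed the threshold (adjusted p = 0.0981), although 1 of its 3 probe sets passed it. PRDM1, the repressor that drives plasma cell differentiation, lay at 7.23 in both types (difference 0.00, adjusted p = 0.99), and SDC1, the plasma cell surface proteoglycan CD138, differed by 0.11 (adjusted p = 0.678). XBP1, which drives the secretory programme, had a difference of 1.25 (adjusted p = 0.585) that was -0.37 against Namalwa alone (dataset as a block, or published dataset), and adjusted p over all alternatives ran from 0.209 to 0.962. TNFRSF17, the receptor BCMA, missed the threshold (-3.82, adjusted p = 0.0502) and passed it without Namalwa (adjusted p = 0.0359, range 4.8e-05 to 0.19). It also passed without Namalwa replicate 1 (0.0434), L1236 replicate 1 (0.0492), SU-DHL4 replicate 1 (0.0497) or SU-DHL6 replicate 2 (0.0476), without dim probe sets (0.0297), with an intensity trend (0.0448) and by gene means (0.0451). Of 19 measured genes of the plasma cell list, 0 were higher and 2 lower, and 3 were higher and 4 lower when adjusted over the list alone (median -0.05, camera adjusted p = 0.336). By fry, which asks whether the members move one way on balance and not whether they differ from other genes, this list passed in the lower direction (adjusted p = 0.0176, range over all alternatives 0.0176 to 0.832). JCHAIN kept its call without any 1 line and with the dataset as a block (adjusted p = 0.00894), which sets the Hodgkin lines against Namalwa alone. Within the published dataset, where the spread is that of the Hodgkin lines only, adjusted p was 0.0378 for JCHAIN and 0.046 for CD38. CD38 was lost without any 1 of KM-H2, L1236, L428, Namalwa and SU-DHL6 (adjusted p = 0.0945 without Namalwa, range over all alternatives 1.0e-05 to 0.21) and with the dataset as a block (0.21).

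Among 30 measured genes of the secretory pathway and unfolded protein response, 16 had higher means in the Hodgkin lines, and 0 passed the threshold in either direction, over all probe sets or adjusted over the list alone (median 0.08, camera adjusted p = 0.201). By fry's test for change in either direction, which does not compare a list with other genes, the list passed (adjusted p = 0.00275). Most of the 24 lists passed that test, so this is not particular to the secretory list. CANX, a chaperone of the endoplasmic reticulum, had the smallest p, with a difference of 0.67 (adjusted p = 0.111), followed by HYOU1 (1.16, adjusted p = 0.12), SPCS2 (-0.63, adjusted p = 0.193) and SEC61A1 (0.45, adjusted p = 0.213). The line means of the types did not overlap in these 4 genes. They were picked by smallest p, which favours such genes, so this adds no support. Among the immunoglobulin genes, 0 of 8 passed in either direction, also when adjusted over the list alone, while the list as a whole was lower (median -0.49, camera adjusted p = 0.0211, but adjusted p = 0.354 with an estimated correlation) and lost its call by fry (adjusted p = 0.123) and without L428 (0.0735, range over all alternatives 8.6e-05 to 0.354). Their probe sets read several near-identical genes and are uncertain. IGHM, the mu heavy chain, lay at 6.85 to 7.17 in the Hodgkin lines and 7.0 in SU-DHL4, against 12.6 in Namalwa and 13.0 in SU-DHL6 (difference -3.85, adjusted p = 0.383), and passed the threshold without SU-DHL4 (-5.78, adjusted p = 0.0106, range over all alternatives 0.0106 to 0.632). IGKC, the kappa light chain, had a difference of -2.05 (adjusted p = 0.22) and passed without Namalwa (-2.72, adjusted p = 0.0212, range 0.00597 to 0.481).

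Among NF-kB targets, Hodgkin markers and the AP-1 family, 5 genes were higher in the Hodgkin lines. ICAM1, an adhesion molecule and NF-kB target, was 3.4-fold higher (log2 difference 1.77 ± 0.19 SE, adjusted p = 0.0288, n = 3 lines per type), and NFKB2, which encodes the NF-kB subunit p52, was 3.47-fold higher (1.80 ± 0.24, adjusted p = 0.0464). CCL5, a T-cell attracting chemokine, was 13-fold higher (3.70 ± 0.25, adjusted p = 0.0114). FUT4, the enzyme that makes the Hodgkin marker CD15, was 2.67-fold higher (1.41 ± 0.13, adjusted p = 0.019), and ATF3, a stress-induced member of the AP-1 network, 11.4-fold higher (3.51 ± 0.30, adjusted p = 0.0169). Of 25 measured NF-kB targets, 2 were higher and 0 lower, and 6 were higher when adjusted over the list alone (median 1.19, camera adjusted p = 4.18e-06, but adjusted p = 0.115 with an estimated correlation). Of 24 Hodgkin markers, cytokines and checkpoint ligands, 2 were higher and 0 lower, and 7 were higher when adjusted over the list alone (median 1.20, camera adjusted p = 6.23e-07), a call that held with an estimated correlation (adjusted p = 0.0318). The AP-1 family had 1 higher gene of 11 and 3 when adjusted over the list alone (median 0.37, camera adjusted p = 0.00162, but adjusted p = 0.186 with an estimated correlation). In the JAK-STAT pathway 0 of 21 genes passed and 3 were higher when adjusted over the list alone (median 0.58, camera adjusted p = 0.00672, but adjusted p = 0.186 with an estimated correlation), and with the dataset as a block the list lost its call (adjusted p = 0.079, range 0.00063 to 0.186).

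Several well-known Hodgkin markers did not pass the test although their Hodgkin means lay above the B-cell means. TNFRSF8, the receptor CD30, ranged from 8.0 in L1236 to 10.4 in L428 against 7.02 to 7.05 in the B-cell lines (difference 2.15, adjusted p = 0.203), and CCL17, the chemokine TARC, from 7.25 in KM-H2 to 11.9 in L428 against 5.56 to 5.81 (difference 3.73, adjusted p = 0.254). CCR7, a lymph node homing receptor, had a difference of 4.84 (adjusted p = 0.0839, and 0.0487 without dim probe sets, range 0.00024 to 0.557), and SOCS1, a feedback inhibitor of JAK signalling, one of 2.38 (adjusted p = 0.0908). FSCN1, an actin-bundling protein used as a Hodgkin marker, had 4.32 (adjusted p = 0.0534) by its representative probe set and passed by the other. The representative passed without L428 (adjusted p = 0.0229), KM-H2 replicate 1 (0.0499) or L1236 replicate 2 (0.0462), without dim probe sets (0.0304) and with an intensity trend (0.0465), as did the mean of both probe sets (0.0189), with a range over all alternatives of 5.8e-05 to 0.445. LGALS1, the lectin galectin-1, had 4.05 (adjusted p = 0.0637) and passed without Namalwa (adjusted p = 0.0487), SU-DHL6 replicate 2 (0.0413) or dim probe sets (0.0349), with a range of 0.00014 to 0.181. Calls of this group were lost without single lines, where fewer lines also remain to test with. The called genes kept their sign without any 1 line, with differences of 1.54 to 1.98 for NFKB2 and 1.62 to 1.93 for ICAM1. CCL5 was lost without SU-DHL4 or SU-DHL6 (adjusted p = 0.0525 without SU-DHL4, range over all alternatives 3.5e-07 to 0.19). FUT4 was lost without any 1 of L1236, L428, Namalwa and SU-DHL4 (0.077 without SU-DHL4, range 3.0e-06 to 0.159). ATF3 was lost without any 1 of L428, Namalwa, SU-DHL4 and SU-DHL6 (0.077 without SU-DHL4, range 1.3e-06 to 0.243). ICAM1 was lost without any 1 of L1236, Namalwa, SU-DHL4 and SU-DHL6 (0.119 without SU-DHL4, range 1.6e-05 to 0.314). NFKB2 was lost without any 1 of the 6 lines (0.121 without L1236, range 9.8e-05 to 0.23) or without any 1 of KM-H2 replicate 2 (0.0524), L1236 replicate 2 (0.0504), Namalwa replicate 2 (0.0865) and SU-DHL6 replicate 2 (0.0583). It was also lost with values raised to a floor (0.0559). Only 1 of the 3 probe sets of NFKB2 passed and 2 had the same sign, and by their mean the difference was 0.86 (adjusted p = 0.144). With the dataset as a block CCL5 (adjusted p = 0.0956), FUT4 (0.121), ATF3 (0.138), ICAM1 (0.2) and NFKB2 (0.23) did not pass.

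**Figure D2:**
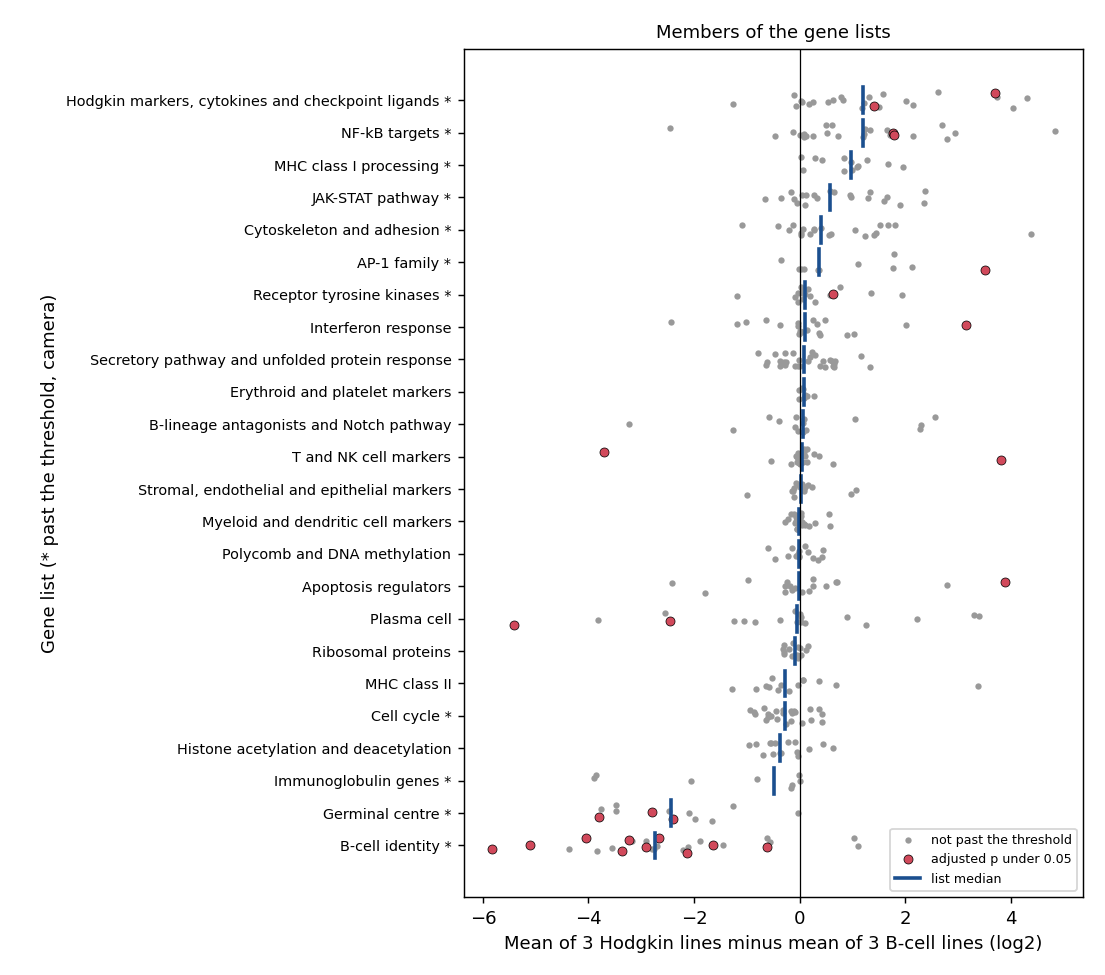
Mean of the 3 Hodgkin lines minus mean of the 3 B-cell lines (log2, horizontal axis) for each measured member of the 24 lists (vertical axis), with members past the threshold in red, others in grey, the list median as a bar and an asterisk on the 11 lists past the threshold by camera at the preset correlation. B-cell identity (median -2.73) and germinal centre genes (-2.44) lie lowest and Hodgkin markers (1.20) highest, the 3 lists that also passed with an estimated correlation, and NF-kB targets (1.19), next to highest, did not (adjusted p = 0.115).

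Among called genes, the largest differences in each direction were as follows. CCND2, a cyclin of the G1 phase, was 56.4-fold higher in the Hodgkin lines, at 11.4 ± 0.51 (SD, n = 3) against 5.54 ± 0.05 (log2 difference 5.82 ± 0.26 SE, adjusted p = 0.00499). MAGEB2, a cancer-testis antigen (4.66, adjusted p = 0.0276), IL1R2, the decoy receptor of interleukin-1 (4.55, adjusted p = 0.0314), and BATF3, a transcription factor of the AP-1 superfamily (4.54, adjusted p = 0.0316), followed. Also higher were the protease subunit CAPN2 (4.26, adjusted p = 0.0101), DRC9 (4.21, adjusted p = 0.0114), the epithelial keratin KRT7 (4.04, adjusted p = 0.0301), NIBAN1 (3.99, adjusted p = 0.0257), the death receptor FAS (3.88, adjusted p = 0.029) and GATA3, a master regulator of T helper cells (3.81, adjusted p = 0.0326). Besides the B-cell genes, SEL1L3 (-4.57, adjusted p = 0.0229), COCH (-4.25, adjusted p = 0.00751), the actin-binding COTL1 (-4.11, adjusted p = 0.0437), RGCC (-4.05, adjusted p = 0.0305) and NCF1, a subunit of the phagocyte oxidase whose probe set may also read its near-identical copies (-3.88, adjusted p = 0.0114), were lowest. CCND2, CAPN2, COCH and NCF1 kept their calls without any 1 line. With the dataset as a block CCND2 (adjusted p = 0.046) and COTL1 (0.0281) passed and the other 13 genes of this group did not, and COTL1 did not pass without SU-DHL6 replicate 2 (0.054). Against Namalwa alone within the published dataset none of the 15 genes passed (0.135 for CCND2). MAGEB2 and KRT7 were lost without any 1 of L1236, Namalwa, SU-DHL4 and SU-DHL6. With values raised to a floor KRT7 (3.55, adjusted p = 0.0502) and COTL1 (adjusted p = 0.0558) did not pass. By the mean of a gene's probe sets the difference was smaller for KRT7 (2.03, where 1 of 2 probe sets passed), CCND2 (3.74) and CAPN2 (2.20), and all 3 kept their calls. IL1R2 and NIBAN1 were lost without any 1 of L428, Namalwa, SU-DHL4 and SU-DHL6. BATF3 and GATA3 were lost without any 1 line but KM-H2, and FAS and COTL1 without any 1 line but Namalwa. DRC9 was lost without SU-DHL4 or SU-DHL6, SEL1L3 without any 1 of L1236, L428, SU-DHL4 and SU-DHL6, and RGCC without any 1 of the 6 lines. Their highest adjusted p without 1 line ran from 0.0525 for DRC9 (without SU-DHL4) to 0.151 for COTL1 (without SU-DHL4), and over all alternatives the highest of these genes' adjusted p was 0.355 (IL1R2 within the published dataset).

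**Figure D3:**
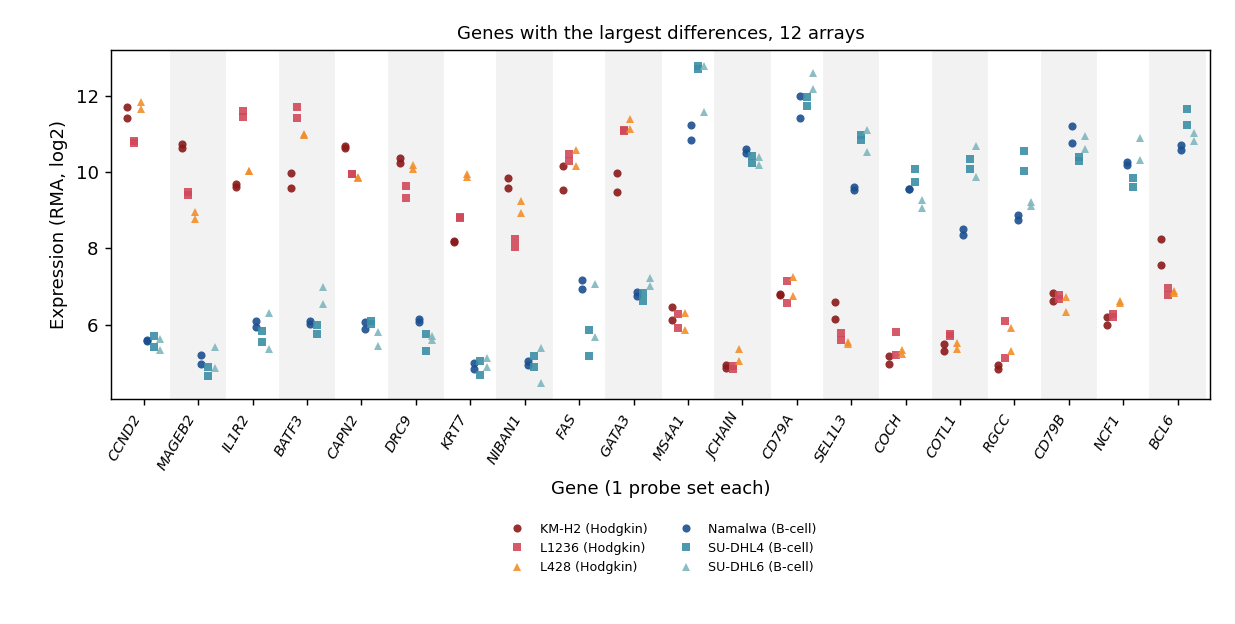
RMA log2 expression (vertical axis) of the 10 genes with the largest positive and the 10 with the largest negative difference among called genes (horizontal axis), with 1 point per array, coloured and shaped by cell line. CCND2 averages 11.4 in the Hodgkin and 5.54 in the B-cell lines, and JCHAIN 4.99 and 10.4.

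All 13 measured genes of MHC class I processing had a higher mean in the Hodgkin lines, although 0 passed the threshold alone or when adjusted over the list alone (median 0.97, camera adjusted p = 0.00162, but adjusted p = 0.354 with an estimated correlation). TAP1, a subunit of the peptide transporter, had a difference of 1.95 (adjusted p = 0.203), and PSMB9, an immunoproteasome subunit, one of 1.68 (adjusted p = 0.222). The list also lost its call by fry (adjusted p = 0.188) and with the dataset as a block (0.14, range over all alternatives 4.4e-05 to 0.354). In MHC class II, 0 of 14 genes passed in either direction or when adjusted over the list alone (median -0.28, camera adjusted p = 0.567). CIITA, its master regulator, differed by 0.07 (adjusted p = 0.669). Its probe set lay between 7.24 and 7.55 on all 12 arrays, so whether it follows the level of the transcript could not be told. HLA-DQA1 lay at 11.5 in KM-H2 and 11.6 in L428, against 6.39 in L1236 and 6.42 to 6.52 in the B-cell lines (difference 3.38, adjusted p = 0.393), and passed without L1236 (5.11, adjusted p = 0.0012, range over all alternatives 0.0012 to 0.96). Probe sets of the HLA genes read alleles unequally and can read related genes, so their levels are uncertain.

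**Figure D4:**
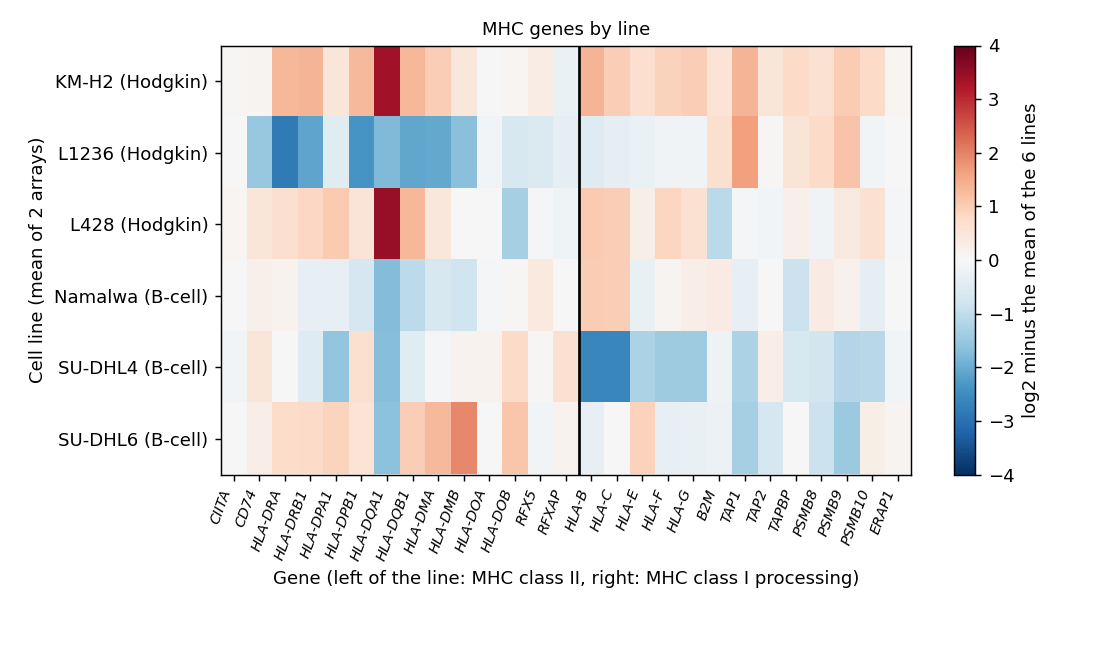
Heat map of MHC class II genes (left of the line) and MHC class I processing genes (right) in the 6 cell lines, with colour giving the line mean of 2 arrays minus the mean of the 6 lines (log2). HLA-DQA1 stands out as high in KM-H2 (11.5) and L428 (11.6) against 6.39 in L1236.

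Further lists held few called genes. Of the interferon response genes, IFITM1, an antiviral membrane protein, was 8.88-fold higher (log2 difference 3.15, adjusted p = 0.0156), and it alone of 20 measured genes passed, also when adjusted over the list alone (median 0.10, camera adjusted p = 0.157). IFITM1 was lost without Namalwa, SU-DHL4 or SU-DHL6 (adjusted p = 0.0717 without SU-DHL4, and 0.13 with the dataset as a block, range 5.9e-06 to 0.241), and the list passed without KM-H2 (adjusted p = 0.0437) or without Namalwa (0.00884, range over all alternatives 0.00884 to 0.672). In the cytoskeleton and adhesion list 0 of 21 genes passed, also when adjusted over the list alone, while the list was higher (median 0.40, camera adjusted p = 0.00955, but adjusted p = 0.256 with an estimated correlation and 0.127 by fry, range 0.00205 to 0.256). Its VIM, the intermediate filament vimentin, had a difference of 4.38 (adjusted p = 0.255) and passed without SU-DHL6 (5.94, adjusted p = 0.03, range 0.00969 to 0.522). Of 17 receptor tyrosine kinases, only the collagen receptor DDR2 passed (0.64, adjusted p = 0.0452), also when adjusted over the list alone. DDR2 was lost without any 1 of the 6 lines (adjusted p = 0.163 without SU-DHL4), with the dataset as a block (0.281) and without any 1 of KM-H2 replicate 2 (0.0529), L1236 replicate 2 (0.149), L428 replicate 1 (0.0661), Namalwa replicate 1 (0.052) and SU-DHL4 replicate 2 (0.0581). It was also lost without dim probe sets (0.0553), with an intensity trend (0.0619) and with a fold minimum of 2, and its adjusted p over all alternatives ran from 0.0004 to 0.395. This list (median 0.10, camera adjusted p = 0.0479, but adjusted p = 0.354 with an estimated correlation) lost its call without SU-DHL4 (0.163) or SU-DHL6 (0.08), with arrays centred on their medians (0.0521), by fry (0.123) and with the dataset as a block (0.195), over a range of 0.0348 to 0.354. Cell cycle genes had 0 of 24 past the threshold, also when adjusted over the list alone, and the list was lower (median -0.28, camera adjusted p = 0.0492, but adjusted p = 0.672 with an estimated correlation). That call was lost without KM-H2 (0.535), L1236 (0.184), Namalwa (0.119) or SU-DHL4 (0.234), with arrays centred (0.072), with the mean over probe sets (0.0674), by fry (0.43) and with the dataset as a block (0.0597). Over all alternatives its adjusted p ran from 0.00011 to 0.672. Of 18 apoptosis regulators only FAS was higher, and 5 were higher and 3 lower when adjusted over the list alone (median -0.02 but mean 0.16, direction of the test up, camera adjusted p = 0.48).

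Chromatin regulators showed no call by gene. Of 16 measured genes of histone acetylation and deacetylation 0 passed, with 1 higher and 1 lower when adjusted over the list alone (median -0.36, camera adjusted p = 0.0677), while by fry the list passed in the lower direction (adjusted p = 0.0176, range over all alternatives 0.0176 to 0.256). The acetyltransferase EP300 had a difference of -0.82 (adjusted p = 0.139). Of 15 genes of the Polycomb and DNA methylation list 0 passed, also when adjusted over the list alone (median -0.01 but mean 0.01, direction of the test up, camera adjusted p = 0.813), with -0.60 for the maintenance methyltransferase DNMT1 (adjusted p = 0.223). Of 15 B-lineage antagonists and Notch pathway genes 0 passed, with 3 higher and 3 lower when adjusted over the list alone (median 0.06, camera adjusted p = 0.813). In that list ID2, an inhibitor of E-box transcription factors, had a difference of 2.29 (adjusted p = 0.102), and ID3, of the same family, -3.24 (adjusted p = 0.113, with 0.0209 without Namalwa, 0.015 with the dataset as a block and 0.0378 within the published dataset, range 0.00075 to 0.252). MYC had a difference of -1.36 (adjusted p = 0.173). Ribosomal protein genes had 0 of 15 past the threshold, also when adjusted over the list alone (median -0.09, camera adjusted p = 0.157).

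By camera, none of the 4 lists of other cell types passed the threshold as a group. By fry's test for change in either direction, which most of the 24 lists passed, 2 of these did. They were T and NK cells (adjusted p = 2.5e-05) and stromal, endothelial and epithelial cells (0.0485). The myeloid and dendritic list (0.561) and the erythroid and platelet list (0.0563) did not pass it. In the T and NK cell list GATA3 was higher and LCK, a proximal T-cell receptor kinase that germinal centre B cells can also express, was lower (-3.70, adjusted p = 0.0362), with the other 20 of 22 not past the threshold and 1 higher and 2 lower when adjusted over the list alone (median 0.05, camera adjusted p = 0.689). LCK was lost without any 1 line but Namalwa (adjusted p = 0.147 without SU-DHL4 and 0.0795 with the dataset as a block, range 2.2e-05 to 0.147), and GATA3 without any 1 line but KM-H2 (0.134 without SU-DHL4 and 0.213 with the dataset as a block, range 1.1e-05 to 0.334). Of 24 myeloid and dendritic cell markers 0 passed, also when adjusted over the list alone (median -0.01 but mean 0.03, direction of the test up, camera adjusted p = 0.917). The same held for 16 stromal, endothelial and epithelial markers (median 0.03, camera adjusted p = 0.653) and for 8 erythroid and platelet markers (median 0.08, camera adjusted p = 0.135).

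In all, 273 of 22215 probe sets (1.23%) passed the threshold, 98 higher and 175 lower in the Hodgkin lines, and 3209 (14.4%) had an unadjusted p under 0.05. The called probe sets named 203 genes, and by representative probe set 56 genes were higher and 104 lower. The line means of the types did not overlap for all 273 called probe sets and for 5023 of those tested (22.6%). Over all groupings of the lines the average share is 10%. Probe sets vary together and the share in other groupings was not computed, so whether 22.6% exceeds chance was not tested. Of the 24 lists, 11 passed the threshold with the preset correlation, 3 with an estimated correlation (B-cell identity, germinal centre and Hodgkin markers), 8 by fry and 7 with the dataset as a block. The number of calls depended on which lines entered, and a fit without 1 line also has fewer lines to test with. With the dataset as a block, a difference of the Hodgkin lines from Namalwa alone, 45 probe sets passed (4 higher, 41 lower; 25 of them among the 273). Within the published dataset the difference is the same and no B-cell spread enters, and 46 passed (1 higher, 45 lower; 17 among the 273). Leaving out 1 line gave 244 probe sets without KM-H2 (147 higher, 97 lower), 153 without L1236, 86 without L428, 146 without Namalwa, 42 without SU-DHL4 (7 higher, 35 lower) and 66 without SU-DHL6. Without SU-DHL6 replicate 2, the array whose 3' to 5' differences stood apart, 241 passed, 209 of them among the 273. Of the 33 named genes that passed, 9 also passed without any 1 line. Against Namalwa alone, 8 passed with the dataset as a block and 5 within the published dataset, with the spread of the Hodgkin lines only. The authors' deposited table gave 2994 probe sets with an adjusted p under 0.05, 1165 higher and 1829 lower, and all 273 were among them. The log2 differences of that table equalled those computed here to within 5.0e-08, and its p-values equalled those of a fit to 12 independent arrays to within a relative difference of 0.00455, a fit that counts arrays and not lines as replicates.

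Each line was next set against the mean of the other 2 lines of its type, so comparisons within a type share their lines and mirror each other in part. KM-H2 differed most from the other Hodgkin lines, with 1560 probe sets past the threshold (802 higher, 758 lower). MMP12, the macrophage metalloelastase, was 65.6-fold higher in KM-H2 (log2 difference 6.04 ± 0.09 SE, adjusted p = 4.2e-10, 2 arrays per line), at 11.2 against 5.25 in L1236 and 5.16 in L428. The cancer-testis antigens MAGEA4 (5.52), MAGEA6 (5.14) and MAGEA1 (5.13) were higher too, although their probe sets are likely to read related family members and are uncertain. CR2, the complement receptor CD21, had a difference of 5.32 (adjusted p = 9.9e-09). PERP, a desmosomal membrane protein (-5.17), SNX7 (-4.99), NDST4 (-4.87), the collagen hydroxylase subunit P4HA2 (-4.79) and EIF5A (-4.57, a gene with pseudogene copies) were lowest. For EIF5A the probe set lay at 7.10 in KM-H2 and 11.5 to 11.9 in the other Hodgkin lines (adjusted p = 1.6e-05).

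L1236 differed from KM-H2 and L428 in 1417 probe sets (734 higher, 683 lower). FCER1A, the alpha chain of the high-affinity IgE receptor, lay at 12.7 in L1236 and at 4.27 to 4.40 in the other 5 lines, a 330-fold difference within the Hodgkin lines (log2 difference 8.37 ± 0.07 SE, adjusted p = 4.4e-12, 2 arrays per line). POU2AF1 was 48.4-fold higher (5.60, adjusted p = 3.0e-08), followed by SULF1, an extracellular sulfatase (5.57), the steroid-converting enzyme AKR1C3 (5.18) and NDST4 (5.16). HLA-DQA1 was 36.7-fold lower (-5.20, adjusted p = 1.8e-08), followed by BAG2 (-4.35), GSTO1 (-4.28), TSPYL1 (-4.04) and MCUB (-3.90). L428 differed in 1247 probe sets (647 higher, 600 lower). TRDV3, a T-cell receptor delta segment (4.83, adjusted p = 8.6e-10), RIN2 (4.65), HEBP2 (4.36), the protease inhibitor TFPI2 (4.32) and ASS1, an enzyme of arginine synthesis (4.30), were higher. PLS3, the actin bundler plastin 3, was 61.8-fold lower (-5.95, adjusted p = 2.5e-10), followed by CEP15 (-4.91), CLIC2 (-4.32) and CYP1B1 (-4.31), and the difference of FCER1A (-4.28) arose from its level in L1236.

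The B-cell lines differed less among themselves. Namalwa departed from the SU-DHL lines in 777 probe sets (427 higher, 350 lower). PLAC8 was 60.3-fold higher (log2 difference 5.91 ± 0.08 SE, adjusted p = 3.2e-10, 2 arrays per line), followed by the protein kinase A subunit PRKAR2B (5.34), the pseudogene BMS1P20 (4.96), the T-cell receptor beta constant region TRBC1 (4.07) and SMAD1, a mediator of BMP signalling (4.04). The probe set named for BMS1P20 is of a kind that can also read other sequences, so which transcript it measured is uncertain. KANK1 (-3.97), the translation factor subunit EIF2S3 (-3.80, with the duplicates of Namalwa 1.18 apart), TOX (-3.49), ZNF804A (-3.49) and MYO1E (-2.93) were lowest. Because Namalwa and the SU-DHL lines came from different datasets, dataset and line cannot be told apart here. Dataset can also enter the comparisons of SU-DHL4 and SU-DHL6, since Namalwa is part of the mean each is set against.

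SU-DHL4 differed from the other B-cell lines in 766 probe sets (418 higher, 348 lower). TUBB6, a beta-tubulin (4.53 ± 0.10 SE, adjusted p = 1.1e-08, 2 arrays per line), ZMIZ1 (4.02), EIF2S3 (3.69), CD99 (3.44) and TOX (3.35) were higher. IGHM was 55.3-fold lower (-5.79, adjusted p = 1.9e-09). The lambda light chain gene IGLC1 (-4.36) and a lambda variable gene (-4.0), which can be read by each other's probes, were lower too, as were the deubiquitinase UCHL1 (-4.80) and PHGDH, the first enzyme of serine synthesis (-3.47). SU-DHL6 differed in 891 probe sets (357 higher, 534 lower). TUBB2B (5.04, adjusted p = 4.1e-06), VIM (4.69), CUX2 (4.07), CHI3L2 (3.5) and STAG3 (3.37) were higher, and the transcription factors TCF4 (-4.18, adjusted p = 1.4e-07) and MEF2C (-4.04), SCRN1 (-3.27), LRIG1 (-3.08) and DSTN (-2.90) were lower. The duplicates of SU-DHL6, 1 of them the array whose 3' to 5' differences stood apart, lay 1.61 apart for DSTN, 1.44 for CHI3L2 and 1.03 for STAG3. The adjusted p-values of these 6 comparisons cover only the spread between duplicate arrays, and the named genes kept their calls under all alternatives tried for them.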

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

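The test of the dataset difference, on the position of Namalwa, was chosen only after the result it bears on was seen, and the count of splits was fixed earlier. Dataset and lymphoma type overlapped in part for the 273 probe sets that differed between Hodgkin and B-cell lines. If the dataset alone produced them, Namalwa, which shares the published dataset with the Hodgkin lines, would lie near the Hodgkin lines. Over the 146 probe sets called without Namalwa, its median position was 0.748 on a scale with the Hodgkin mean at 0 and the mean of the SU-DHL lines at 1 (lower quartile 0.543, upper quartile 0.988), and in 114 (78.1%) it lay nearer the SU-DHL lines. This argues against the dataset difference as the whole cause, while a contribution to single probe sets stays open, as does the difference between lymphoma types that the design names. Of the 10 splits of the 6 lines into 3 and 3, only 1, the real one, gave as many probe sets (273, with 1 in the highest other split), and 10 splits are too few for a share under 0.05.

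Among 340 groups of 6 arrays of a type (170 genes), 11 held an array that stood apart from the others. This was judged by the ratio of its gap to the group's range, and no explanation was tested. For independent values chance gives about 5% of groups, a rate that need not hold here because the arrays come as duplicates of lines. In the Hodgkin arrays those that stood apart were SDC1 on L428 replicate 1 (ratio 0.697, log2 signal 7.60 with the nearest array at 7.29) and STAT5A on L428 replicate 2 (0.699, 11 with the nearest at 9.72). Further ones were SOCS1 on KM-H2 replicate 2 (0.689, 8.03 with the nearest at 8.59), UCHL1 on KM-H2 replicate 2 (0.690, 6.64 with the nearest at 6.35) and RPL10A on KM-H2 replicate 1 (0.633, 12.4 with the nearest at 12.3). In the B-cell arrays they were FSCN1 (0.856, 6.40 with the nearest at 6.14) and BATF (0.638, 9.85 with the nearest at 8.35) on SU-DHL6 replicate 1. Others were KAT6A (0.636, 10.0 with the nearest at 9.57) and EIF5A (0.675, 9.81 with the nearest at 11.5) on SU-DHL6 replicate 2, GP9 on SU-DHL4 replicate 2 (0.628, 7.36 with the nearest at 7.62) and TRDV3 on Namalwa replicate 1 (0.642, 4.78 with the nearest at 4.68). SU-DHL6 replicate 2 is the array with the 3' to 5' differences described for GAPDH and ACTB. In 0 of 714 combinations of 119 genes and 6 pairs of lines of a type did limma place both lines past the threshold on opposite sides of the mean of the other type.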

How the results depend on the processing

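No alternative was added after the data were seen. In the line comparisons the named genes kept direction and call in all 943 combinations of gene and alternative. In the comparison of types, genes past the threshold kept direction and call in 818 combinations and lost the call in 172, and genes not past it stayed so in 2373, passed in 186 and changed sign in 13. For lists, 94 calls were kept and 27 lost, and of those not past the threshold 125 stayed, 4 passed and 14 changed direction. The main count was 273 probe sets (98 higher, 175 lower). Taking 12 arrays as independent gave 2996 (1166 higher, 1830 lower; 273 shared), and the line as a random block 1605 (619 higher, 986 lower; 265 shared), since both count arrays within a line as further replicates. With the replicate block added to it, 1379 passed (509 higher, 870 lower; 261 shared), and the line comparisons with the replicate block gave 1560, 1416, 1244, 772, 759 and 896 in the order KM-H2, L1236, L428, Namalwa, SU-DHL4, SU-DHL6. The replicate numbers do not pair the samples: deviations of equal-numbered arrays correlated across probe sets at -0.443 to 0.296, over 0.1 in 4 of 15 pairs of lines. The dataset as a block gave 45 (4 higher, 41 lower) and the published dataset alone 46 (1 higher, 45 lower), with XBP1 at -0.37 in both. These fits set the Hodgkin mean against Namalwa alone, and for XBP1 Namalwa (9.51) lay above the Hodgkin mean (9.14) while the SU-DHL4 (6.38) and SU-DHL6 (7.76) levels did not enter. Leaving out 1 line or array gave 42 to 273 probe sets, 7 to 147 higher and 35 to 176 lower. Most moves came from whole lines, with 244 without KM-H2 (97 lower), 153 without L1236, 86 without L428, 146 without Namalwa, 42 without SU-DHL4 and 66 without SU-DHL6, against 212 to 273 without single arrays. PRDM1, near 0 in the main comparison, ran from -0.098 to 0.075 without 1 line or array and was -0.0059 with arrays centred on their medians. Raising values to a floor turned TLR4 (0.012), KRT19 (0.033) and COL3A1 (0.033), which lie near the lowest signals. Other counts stayed within 1.5 times, with 268 for centred arrays, 224 for repeated quantile normalisation, 220 with the floor, 327 without dim probe sets, 244 with an intensity trend and 200 with a fold minimum. The mean over a gene's probe sets gave 188, a count of genes that cannot be set against 273 probe sets, where 160 genes had a called representative with p adjusted over probe sets. Without the fold minimum the line comparisons gave 5548, 4994, 4894, 3372, 3184 and 3935 in the same order, as a fold minimum removes small differences. Of 11 lists past the threshold, 3 passed with an estimated correlation and 7 with the dataset as a block. Lists near 0 changed direction without a call: with the dataset as a block, B-lineage antagonists and Notch (adjusted p = 0.526), myeloid (0.689), MHC class II (0.954), Polycomb (0.733) and interferon (0.134); by fry, myeloid (0.973); with arrays centred, myeloid (0.987). Without 1 line, adjusted p ran from 0.353 to 0.986 for the Notch list, 0.375 to 0.977 for T and NK cells, 0.715 to 0.915 for myeloid cells, 0.0698 to 0.81 for MHC class II and 0.61 to 0.921 for Polycomb. By fry the plasma cell and histone acetylation lists passed, both lower (0.0176 each). The cause was not tested for these. Signals near an array's lower quartile (5.64 to 5.75) are not separable from background, so folds that reach into that range are understated.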

Other observations

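The tests of gene lists and of windows within single lines were chosen only after the data were seen, as were the genes named in the first 3 paragraphs, whereas the tests of correlation along the gene order were fixed earlier. L1236 had low MHC class II expression. HLA-DRA, the alpha chain of HLA-DR, lay at 8.56 in L1236 against 12.7 in KM-H2 and 12 in L428 (log2 difference -3.83 ± 0.15 SE, adjusted p = 1.2e-07, 2 arrays per line), HLA-DRB1 had a difference of -3.22, HLA-DPB1 of -3.26, and CD74, the invariant chain of class II molecules, of -1.82. Of 14 class II genes 9 were lower in L1236 and 0 higher (median -1.86, adjusted p = 5.5e-09 over 144 list tests, but adjusted p = 0.373 with an estimated correlation). In the mirrored comparisons 7 were higher in KM-H2 (adjusted p = 4.4e-06, but 0.426 with an estimated correlation) and 7 in L428 (adjusted p = 3.4e-05, but 0.428). Within the B-cell lines, 4 class II genes were lower in Namalwa (median -0.29, adjusted p = 0.0056, but 0.613 with an estimated correlation) and 5 higher in SU-DHL6 (median 0.63, adjusted p = 0.0154, but 0.647).

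Namalwa carried higher interferon-induced transcripts than the SU-DHL lines. MX1, an antiviral GTPase, was 7.6-fold higher (log2 difference 2.93 ± 0.10 SE, adjusted p = 2.2e-07, 2 arrays per line), and OAS2, a sensor of double-stranded RNA, had a difference of 2.19. Of 20 interferon response genes 7 were higher in Namalwa and 0 lower (median 0.51, adjusted p = 7.9e-08, but adjusted p = 0.109 with an estimated correlation), and the dataset of Namalwa differs from that of the SU-DHL lines. In the mirrored comparisons 6 were lower in SU-DHL4 (median -0.37, adjusted p = 0.00108, but 0.373 with an estimated correlation), and in SU-DHL6 2 were higher and 3 lower (adjusted p = 0.0205, but 0.389).

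The B-cell lines also differed in MHC class I, with SU-DHL4 lowest for HLA-B and HLA-C. HLA-C was 8.47-fold lower than in Namalwa and SU-DHL6 (log2 difference -3.08 ± 0.10 SE, adjusted p = 1.7e-07, 2 arrays per line) and HLA-B had a difference of -2.94. Of 13 genes of class I processing 6 were lower and 0 higher (median -0.51, adjusted p = 4.4e-06, but adjusted p = 0.389 with an estimated correlation). The mirrored shift in Namalwa had a larger median, with 5 of 13 higher (0.98, adjusted p = 5.8e-06, but 0.389). Among the Hodgkin lines 1 of the 13 was higher in KM-H2 (median 0.54, adjusted p = 0.00038, but 0.428). Of 25 NF-kB targets 5 were lower in SU-DHL4 (median -0.50, adjusted p = 0.00195, but 0.477). In L428, 4 of 24 cell cycle genes were higher than in the other Hodgkin lines, among them the mitotic kinases AURKB (1.32) and PLK1 (1.28) (median of the list 0.61, adjusted p = 8.6e-07, but adjusted p = 0.373 with an estimated correlation). In KM-H2, 3 were lower (median -0.29, adjusted p = 0.0124, but 0.5). In all, 14 of the 144 list tests within lines passed with the preset and 0 with an estimated correlation, a repeat that is also stricter through its fewer degrees of freedom.

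Genes that neighbour each other in the genome shifted together in single lines. At 11 to 20 places along the order of 11932 genes, deviations of a line from its type correlated at 0.0728 (L1236, the lowest) to 0.0944 (L428). In 6 lines of 6 this was above the highest of 200 shuffles of the gene order (0.00621 to 0.00883). The deviations within a type share their lines and mirror each other in part, so these are not 6 separate observations. The correlation at this distance argues against shared sequence or shared regulation limited to directly adjacent related genes as the whole cause. Shared regulation over longer clusters stays open, because clusters such as the MHC genes were not left out of the test. Differences in copy number between the lines may contribute, as a hypothesis. The lowest correlation of 0.0728 is what such differences need, but it is not particular to them. A bias that varies from array to array along the genome stays open, because the correlation for the difference between the 2 arrays of a line reached 0.521 of the line's own in SU-DHL4, 0.51 in SU-DHL6 and 0.281 in KM-H2. The share was 0.122 in Namalwa, 0.0607 in L1236 and 0.0485 in L428, and only in L1236 and L428 did the correlation between duplicates lie within the shuffles. Such a bias cannot be told apart from the lines' own shifts in SU-DHL4, SU-DHL6 and KM-H2. It can also enter the other lines through their references. Namalwa is set against SU-DHL4 and SU-DHL6, and L1236 and L428 are each set in part against KM-H2.

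Windows of 31 neighbouring genes showed where these shifts lay. The windows of all lines stay open to the bias between arrays, through a line's own arrays or through those of the lines it is set against. In KM-H2 the highest window (TBX5 to UNC119B) had a median log2 difference of 0.87 with 29 of its genes higher, where the extreme of 100 shuffles was 0.47. In Namalwa a window from RPL36AL to GCH1 had a median of -0.60 with 29 genes lower (extreme of the shuffles -0.26), and in SU-DHL4 a window from HLA-E to NCR3, which holds HLA-B and HLA-C, had a median of -0.42 with all 31 genes lower (extreme -0.26). In SU-DHL6 the window from HLA-DQB1 to CUTA had a median of 0.60 (extreme 0.29). A window from CASP8AP2 to SNX3 had a median of -0.54 in L1236 and one from GPR63 to MICAL1 a median of 0.74 in L428. These windows share the genes from GPR63 to SNX3 and come from mirrored comparisons, so they are not separate observations. Both hold PRDM1, whose own signal differed little between the lines, though whether its probe set follows the transcript could not be told. It lay at 6.95 and 7.33 on the arrays of L1236, 7.11 and 7.13 in KM-H2, and 7.44 on both arrays of L428.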
